A study of Homo sapiens with 2 samples.

How the data were processed

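Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and handled with Cell Ranger 2.0.2 and its aligner STAR on the human genome build hg38. The annotation release is not given in the sources used here. Per the labels' protocols, libraries were made with the 10x Chromium 3′ chemistry, version 2, with ERCC spike-in RNA added to each sample. As deposited, the table holds gene counts of the authors: UMIs per gene and cell after their choice of cells and genes, not scaled. The series text speaks of normalized counts merged from single-cell and bulk data, but every value in the table is a whole number with a highest count of 802, so the values were used as raw counts.

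The table has 6387 cells and 21193 entries, of which 88 are ERCC spike-ins and 21105 are genes. A symbol was given for 20880 genes, and 225 had an identifier alone. These 225 took 0.0918% of vehicle and 0.0820% of nutlin-3 UMIs. Every entry was detected in at least 3 cells and every cell had at least 1005 genes, so the authors' filters came before everything reported here. Library and cell agreed between the column names and the authors' cell table for all 6387 cells. Positions come from GENCODE release 29 on GRCh38, which holds 21031 of the genes. UMIs per cell ranged from 1911 to 19329 with vehicle and from 2125 to 19606 with nutlin-3.

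UMIs were summed over the cells of each library and divided by the library's total over genes to give CPM. Ratios are nutlin-3 over vehicle, with exact conditional binomial 95% intervals. Genes with at least 100 UMIs over both libraries were counted as at least 2-fold higher or lower. No gene was tested, since 1 library per group gives no replicate error and cells of a library are not replicates. Where a library had 0 UMIs, the ratio was bounded with 3 counts over that library.

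The text names MDM2, MDM4, CDKN1A, MYCN and CDK4, the 12 genes highest and the 12 lowest by the interval bound nearest to 0, and up to 4 members of each list with a median outside its random lists, ranked the same way in the list's direction. Some genes that this rule picks are not reported here. Other genes named as list members or as exceptions were chosen after their values were seen.

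The 22 gene lists were fixed before the data were examined, as were the comparisons, the naming rule and the alternatives not marked as added. They cover p53 targets of arrest, repair and feedback and of cell death, S phase, G2 and M phase, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear oxidative phosphorylation, adrenergic and mesenchymal neuroblastoma identity, neuronal differentiation, cholesterol synthesis, the unfolded protein and integrated stress response, immediate early and heat shock genes, hypoxia and glycolysis, interferon response, lysosome and autophagy, and markers of leukocytes, endothelium, fibroblasts, Schwann cells and epithelium. Members were called higher or lower at 1.5-fold. Medians were set against 10000 random lists matched on mean CPM in 10 bins, and median intervals come from 1000 Poisson draws.

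For shares of cells, phases, joint detection and spread, each cell was thinned without replacement to 5000 UMIs, and shallower cells were left out. The depth is the 10th percentile of UMIs per cell, rounded down. Shares have exact Clopper-Pearson 95% intervals, and beside a share of 0 the limit of 3 counts is given instead. Phases were scored with scanpy 1.11.5 on log-normalized thinned cells of both libraries together. The Fano factor was taken for p53 targets with a mean of at least 0.1 UMIs per thinned cell. Each library was clustered alone with Leiden at a resolution of 0.5 on 2000 variable genes, 20 principal components and 15 neighbours, and clusters were named only from fixed markers.

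Alternatives changed 1 choice at a time, except that G1 cells were used thinned. They were TMM factors of edgeR 4.0.16 (1.09 for vehicle, 0.917 for nutlin-3) and size factors of DESeq2 1.42.0 (1.07 and 0.935) for scaling, totals without 87 ribosomal protein and 26 mitochondrial genes, UMIs per ERCC UMI, the mean of each cell's own CPM, filters of 20 and 1 UMIs, cells with at most 10% mitochondrial UMIs and at least 1000 genes, removal of Scrublet doublets, thinning before summing, no thinning, thinning to 10000 UMIs, separate phase scoring, a 2-fold size for list members and a Leiden resolution of 1.0. Added after seeing the data were G1 cells only, thinned to 5000 UMIs, removal of a nutlin-3 cluster led by heat shock genes, and removal of the 5% of cells with the most UMIs, 320 in all. Scrublet marked 10 of 6387 cells, 0.157%, far fewer than droplet loading gives, so its calls are taken not to have worked. Whether doublets had been removed earlier is not given in the sources used here, so doublets can remain in all values.

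The steps were tested on simulated data with known ratios before use. All simulated genes with 3-fold or 4-fold differences in either direction passed the 2-fold size, and 0 of 11392 unchanged genes did. The simulated library sums carried Poisson noise alone, without differences between cells or cultures. They check the calculation and do not bear on how many genes pass in the real libraries without a treatment effect. Counting intervals held the true ratio for 95.4% of genes, and 4.5% of unchanged lists fell outside their random lists. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3. Bulk data that the series text mentions were not analysed here.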

Results

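The data are single-cell RNA counts from NGP, an established human neuroblastoma cell line with amplified MYCN and extra copies of MDM2. Cells grown for 48 hours and then kept without serum for 24 hours were given either 8 µM nutlin-3 or its solvent, ethanol, for 24 hours. Nutlin-3 is a small molecule that occupies the p53-binding pocket of MDM2, the ubiquitin ligase that marks p53 for degradation. Droplet libraries with unique molecular identifiers (UMIs) were made from each culture, 1 library per treatment, for a target of about 2000 cells each. The vehicle library held 2977 cells and 25210910 gene UMIs, with a median of 7971 UMIs and 2353 detected genes per cell. The nutlin-3 library held 3410 cells and 25899618 gene UMIs, with a median of 6752 UMIs and 1890 genes. Mitochondrially encoded genes took a median of 5.11% of UMIs per vehicle cell and 4.88% per nutlin-3 cell. Spike-in RNA gave a median of 1528 UMIs per vehicle cell and 1458 per nutlin-3 cell, or 5.62 and 5.27 gene UMIs per spike-in UMI. With 1 library per treatment no difference has a replicate check, no test was made, and every interval given here is a 95% interval for counting error alone.

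The main comparison asked which genes differ in level between nutlin-3-treated and vehicle-treated cells, on UMIs summed over the cells of each library and scaled to equal library totals (CPM). Targets of p53 were higher in the nutlin-3 library and genes of DNA replication and mitosis were lower. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was at 128 CPM with nutlin-3 and 4.76 CPM with vehicle, 26.8-fold higher (22.3 to 32.4). MDM2, itself a p53 target, was at 402 and 189 CPM, 2.13-fold higher (2.05 to 2.20). MYBL2, a transcription factor of the cell cycle, was at 43.3 and 184 CPM, 4.25-fold lower (3.98 to 4.54), and MYCN was at 691 and 1213 CPM, 1.76-fold lower (1.72 to 1.79).

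Among 11588 genes with at least 100 UMIs over both libraries, 175 were at least 2-fold higher and 579 at least 2-fold lower in the nutlin-3 library. The median log2 ratio over all of these genes was −0.27, so the split leans towards lower genes. With edgeR's TMM factor it was 308 higher and 302 lower, with DESeq2 size factors 292 and 326, without ribosomal protein and mitochondrial genes in the totals 252 and 401, and per spike-in UMI 146 and 801. The median over all genes was −0.02, −0.04, −0.11 and −0.37 under these 4 scalings, and each adds a constant to every log2 ratio. Filters of at least 20 and at least 1 UMI gave 408 and 985, and 1379 and 2765.

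The 12 genes ranked highest by the interval bound nearest to 0 were CYP4F3, GDF15, ACTA2, CDKN1A, INPP5D, ENSG00000251095, HSPA6, BBC3, AQP3, GAS6-AS1, LNCTAM34A and PHLDA3. CYP4F3, a cytochrome P450 gene, had 190 UMIs with nutlin-3 and 0 with vehicle, which allows up to 0.119 CPM there, so it was at least 61.6-fold higher, taken against 3 counts over the vehicle library. GDF15, a secreted stress cytokine and p53 target, had 157 and 2 UMIs, a log2 ratio of 6.26 (4.38 to 9.31). INPP5D, an inositol phosphatase gene, had 111 and 2 UMIs and a log2 ratio of 5.76 (3.87 to 8.82). ACTA2, smooth muscle actin, had 324 and 8 UMIs (5.30; 4.31 to 6.53), and AQP3, a water and glycerol channel, had 114 and 4 (4.79; 3.40 to 6.69), with 5.60 once the 5% of cells with the most UMIs were left out. BBC3, which encodes the pro-apoptotic protein PUMA, was 15.6-fold higher (12.9 to 19.0), and PHLDA3, a p53-induced repressor of AKT, was 8.33-fold higher (7.32 to 9.51). Noncoding genes of this group were LNCTAM34A at the miR-34a locus, with a log2 ratio of 3.89 (3.33 to 4.51) or 4.72 when every cell was thinned first, GAS6-AS1, with 4.28 (3.37 to 5.37), and the unnamed antisense gene ENSG00000251095, with 5.14 (3.75 to 7.04). HSPA6, an inducible heat shock gene, had 540 and 27 UMIs, but only 40 nutlin-3 cells and 3 vehicle cells held any, and 2 nutlin-3 cells held 50% or more of the nutlin-3 UMIs.

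On GRCh38, CDKN1A lies on chromosome 6 from 36676460 to 36687339, MDM2 on chromosome 12 from 68808176 to 68850686, and MYCN on chromosome 2 from 15940564 to 15947007. CYP4F3 lies on chromosome 19 from 15640897 to 15662825, GDF15 on chromosome 19 from 18374731 to 18389176, and BBC3 on chromosome 19 from 47220822 to 47232766. LNCTAM34A lies on chromosome 1 from 9182004 to 9196284, and ENSG00000251095 on chromosome 4 from 89551356 to 89726752. Counts are for whole genes, read from transcript 3′ ends.

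The 12 genes ranked lowest were ATAD2, E2F2, TICRR, CEP55, PIF1, MYBL2, ANLN, KIF23, ARHGAP11A, KIF14, MCM10 and HJURP. E2F2, an activator of S phase genes, had a log2 ratio of −2.41 (−2.68 to −2.14). TICRR and MCM10, which act in the firing of replication origins, had −2.44 (−2.88 to −2.03) and −2.00 (−2.21 to −1.80). ANLN, KIF23 and CEP55, which act in cytokinesis, had −2.29 (−2.59 to −1.99), −2.15 (−2.40 to −1.91) and −2.25 (−2.49 to −2.03). ATAD2, a chromatin-bound ATPase of S phase cells, had −2.35 (−2.56 to −2.15).

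Fixed gene lists were then compared with 10000 random lists of the same size and expression level. Of 18 lists with at least 3 measured members, 8 had a median outside the central 95% of their random lists. For lists of unrelated genes 0.9 would fall outside by chance. Members of a list can vary together, so how many would do so here is unknown. Of 30 measured p53 targets of arrest, repair and feedback, 23 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 1.51 (1.37 to 1.58), above all random medians (central 95% −0.45 to −0.10). BTG2, an antiproliferative gene, was 6.40-fold higher (5.28 to 7.81), DDB2 and XPC of nucleotide excision repair had log2 ratios of 2.01 and 0.81, and SESN1 and SESN2 had 2.43 and 2.60. ALDH4A1 and NINJ1 were close to level, at −0.16 and 0.12. Of 10 measured p53 targets of cell death, 5 were at least 1.5-fold higher and 2 at least 1.5-fold lower, with a median of 0.62 (0.54 to 0.70; central 95% −0.55 to 0.06). Besides BBC3, the higher members were TNFRSF10B, a death receptor, at 10.0-fold (5.38 to 20.6), PIDD1 at 7.34-fold (5.59 to 9.80), BAX at 2.20-fold (2.12 to 2.28) and TP53I3, with a log2 ratio of 0.84. The lower ones were SIVA1 at −1.11 and APAF1 at −0.86, and PMAIP1, which encodes NOXA, was at −0.15.

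Cell cycle lists were lower as a whole. Of 41 measured S phase genes, 37 were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median log2 ratio of −1.25 (−1.35 to −1.20; central 95% −0.43 to −0.14). Of 54 measured G2 and M phase genes, 53 were at least 1.5-fold lower and 0 at least 1.5-fold higher, with a median of −1.37 (−1.43 to −1.34; central 95% −0.39 to −0.14). The S phase genes with the lowest bounds were ATAD2, BRIP1, a helicase, at −2.12 (−2.49 to −1.77), MCM6 of the replicative helicase at −1.85 (−2.05 to −1.66) and UHRF1 at −1.72 (−1.86 to −1.60). In the mitotic list they were ANLN, KIF23, HJURP and CDCA2, the last at −2.06 (−2.34 to −1.79). The proliferation marker MKI67 was 3.10-fold lower (2.89 to 3.33), TOP2A 2.56-fold lower (2.46 to 2.67), CCNB1, cyclin B1, 2.13-fold lower (1.97 to 2.30) and PCNA 1.76-fold lower (1.63 to 1.90).

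**Figure D1:**
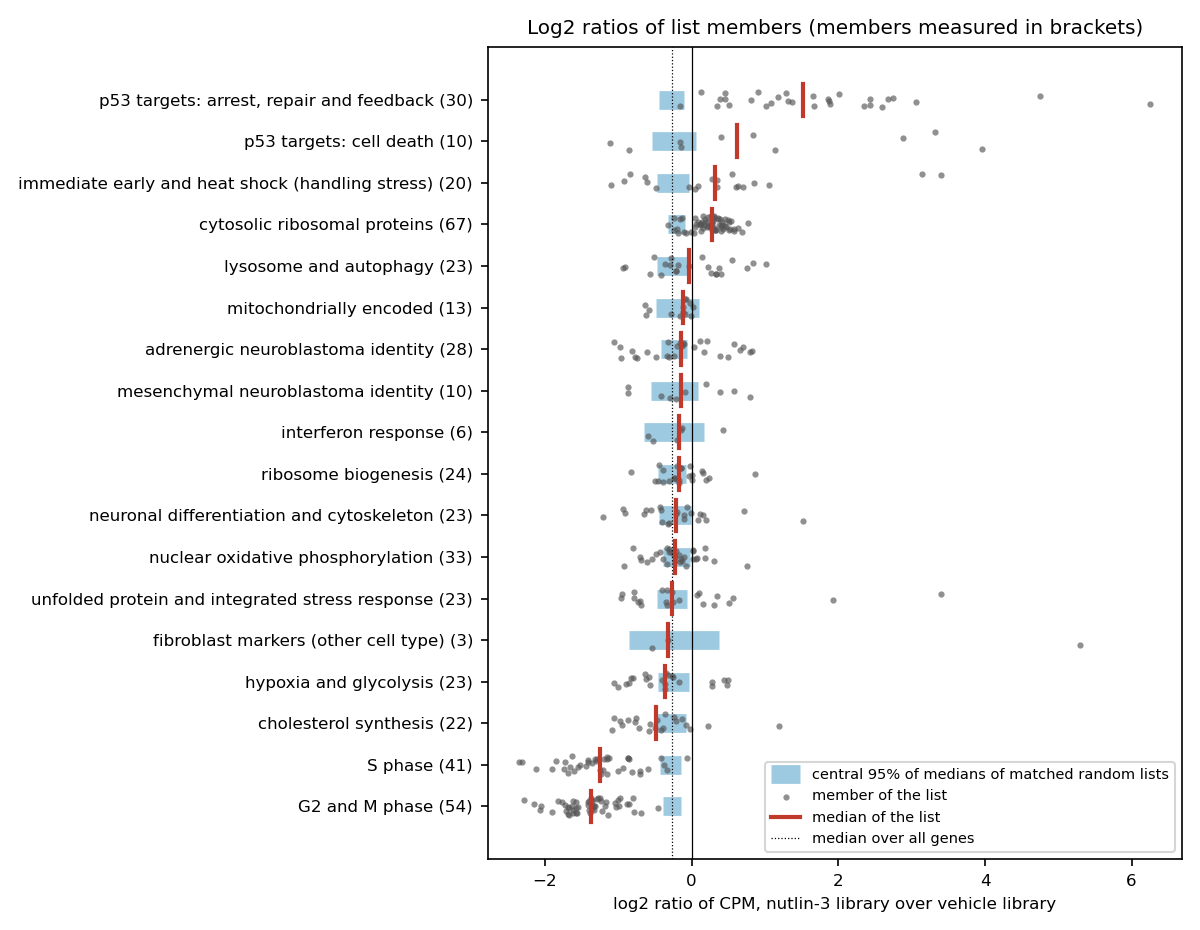
Log2 ratios of CPM, nutlin-3 library over vehicle library (x axis), for the measured members of each fixed gene list (y axis); dots are genes, red bars list medians, blue bars the central 95% of medians of matched random lists, and the dotted line the median over all genes, −0.27. The medians of the p53 target lists, 1.51 and 0.62, lie to the right of their random lists, and those of the cell cycle lists, −1.25 and −1.37, to the left.

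Cytosolic ribosomal protein genes took 36.9% of gene UMIs with nutlin-3 and 30.5% with vehicle. Their median log2 ratio was 0.28 (0.27 to 0.28), above all random medians, yet of 67 genes only RPL5, RPL3 and RPL7A were at least 1.5-fold higher, by 1.71-fold (1.69 to 1.73), 1.60-fold (1.59 to 1.62) and 1.54-fold (1.53 to 1.56). RPL10A followed, with a log2 ratio of 0.58 (0.57 to 0.59). The count of members depends on the setting. With TMM scaling, which raises every log2 ratio, the median was 0.53 and RPL10A passed 1.5-fold too. How many other members passed under TMM scaling is not given here. Among thinned cells called G1 the median was 0.17 and 0 of 67 genes were at least 1.5-fold higher. The family has many near-identical pseudogene copies, so counts of single members are uncertain.

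Of 22 measured cholesterol synthesis genes, 8 were at least 1.5-fold lower and 1 higher, with a median log2 ratio of −0.49 (−0.58 to −0.43), at percentile 1.99 of the random lists. SQLE, which encodes squalene epoxidase, was 1.97-fold lower (1.87 to 2.07), and HMGCS1, an early enzyme of the pathway, was 1.93-fold lower (1.73 to 2.15). TM7SF2, a sterol reductase of the same pathway, had a log2 ratio of 1.19. The median was −0.24 with TMM scaling, where the median over all genes was −0.02.

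Immediate early and heat shock genes, a list fixed as a sign of handling stress, went both ways. Of 20 measured members, 7 were at least 1.5-fold higher and 5 at least 1.5-fold lower, with a median log2 ratio of 0.31 (0.23 to 0.34), above all random medians. ATF3 was 10.5-fold higher (5.68 to 21.7), FOS 8.83-fold (5.17 to 16.2), JUN 2.07-fold (1.85 to 2.32) and DNAJB1 1.55-fold (1.41 to 1.70), while the abundant chaperones HSP90AA1 and HSPE1 had log2 ratios of −1.11 and −0.84. Of the nutlin-3 library's UMIs, 85.3% of those of FOS, 78.2% of ATF3, 72.9% of JUN and 59.7% of DNAJB1, and 102 of the 157 UMIs of GDF15, came from a cluster of 276 cells led by heat shock genes. Without that cluster the list's median was −0.56, JUN was at −0.72 and DNAJB1 at −0.57, and 151 genes were at least 2-fold higher and 542 at least 2-fold lower in all. JUN and DNAJB1 are among the genes that lead the cluster, which was left out of the nutlin-3 library alone, so their fall was fixed in advance. FOS and ATF3 had too few UMIs left and dropped out of that median.

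Lysosome and autophagy genes had a median log2 ratio of −0.04, at percentile 98.4 of lists whose medians were lower still, and the sign depended on the scaling, with 0.21 under TMM and 0.19 under DESeq2 size factors. Of 23 measured members 3 were at least 1.5-fold higher, NEU1 at 1.01, NPC2 at 0.84 and WIPI1 at 0.76, and 2 at least 1.5-fold lower, among them LAMP2, a lysosomal membrane protein gene, 1.88-fold lower (1.54 to 2.30). CTSB and ATG9A were lower by less than 1.5-fold.

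The other lists had medians inside the range of their random lists. Of 28 measured genes of adrenergic neuroblastoma identity, 4 were at least 1.5-fold higher, namely DBH, PHOX2A, CHGA and STMN2, with log2 ratios from 0.66 to 0.82, and 7 at least 1.5-fold lower, among them RET at −0.97 and MYCN at −0.81. Of 10 measured mesenchymal identity genes 1 was higher and 2, TWIST1 and FN1 at −0.86 each, were lower. Of 23 neuronal genes 2 were higher, PRPH, which encodes peripherin, at 1.52 and MAPT at 0.72, and 5 were lower, among them NEFM at −1.21, MAP2 at −0.94 and GAP43 at −0.91. Medians for these 3 lists were −0.14, −0.15 and −0.21, and under TMM scaling they were above 0, at 0.11, 0.10 and 0.04. Hypoxia and glycolysis genes had a median of −0.37, with VEGFA at −1.06 and SLC2A1 at −0.89 among 8 lower members of 23 and 0 higher. Unfolded protein and integrated stress response genes had a median of −0.27, with HSP90B1 at −0.97 but DDIT4 at 1.93. Nuclear oxidative phosphorylation genes had a median of −0.23, ribosome biogenesis genes −0.17, with NPM1 at 0.86, mitochondrially encoded genes −0.12 and interferon response genes −0.17, and these 4 were also above 0 under TMM scaling, from 0.02 to 0.13.

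Markers of other cell types were scarce. Leukocyte markers summed to 48 UMIs with nutlin-3 and 41 with vehicle, endothelial markers to 2 and 2, epithelial markers to 161 and 66 and Schwann cell markers to 548 and 747. Of the fibroblast list 3 genes were measured, PDGFRA at −0.54, PDGFRB at −0.32 and ACTA2 at 5.30. MDM4, a relative of MDM2, was 1.25-fold lower (1.16 to 1.34), a log2 ratio of −0.32. Among thinned cells called G1 it was at 0.02 (−0.42 to 0.49) on 45 vehicle UMIs, an interval that holds the value of all cells. CDK4 was 1.18-fold lower (1.17 to 1.19), with a log2 ratio of 0.01 under TMM scaling.

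Shares of cells with a UMI were compared after every cell had been thinned to 5000 UMIs, which kept 2840 vehicle and 2937 nutlin-3 cells and left out 137 and 473. CDKN1A was detected in 41.3% of nutlin-3 cells (39.5 to 43.1) and 2.22% of vehicle cells (1.71 to 2.83). BBC3 was detected in 27.2% (25.6 to 28.9) and 2.11% (1.62 to 2.71), PHLDA3 in 32.9% (31.2 to 34.7) and 4.86% (4.10 to 5.72), and MDM2 in 81.6% and 59.7%. MKI67 was detected in 14.7% of nutlin-3 cells (13.5 to 16.1) and 41.3% of vehicle cells (39.5 to 43.2), TOP2A in 26.8% (25.2 to 28.4) and 60.4% (58.5 to 62.2), CCNB1 in 13.4% (12.2 to 14.7) and 26.3% (24.7 to 27.9) and PCNA in 16.8% (15.5 to 18.2) and 27.7% (26.1 to 29.4). ACTA2 was detected in 5.99% of nutlin-3 cells (5.16 to 6.91) and CYP4F3 in 3.06% (2.47 to 3.75), against 0.141% (0.0384 to 0.360) and 0 of 2840 vehicle cells, the latter allowing up to 0.106%. JUN and DNAJB1, higher in CPM with nutlin-3, were detected in fewer nutlin-3 cells, 5.75% and 8.00% against 8.24% and 11.5%, so no order is read from these shares. Without thinning CDKN1A was detected in 52.3% of nutlin-3 and 3.29% of vehicle cells, and MKI67 in 19.3% and 53.3%. All cells are of one line, so no cell type lacking these genes was at hand to measure the share that free RNA gives.

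**Figure D2:**
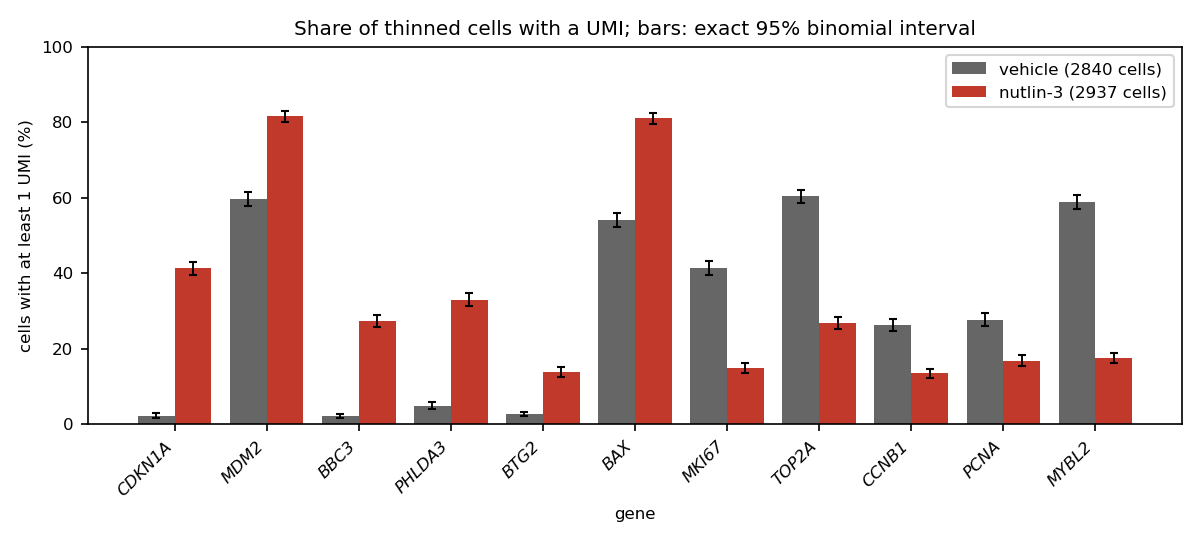
Share of cells with at least 1 UMI (y axis, %) for 11 genes (x axis) after thinning to 5000 UMIs, in the vehicle (grey, 2840 cells) and nutlin-3 (red, 2937 cells) libraries, with exact 95% binomial intervals that cover counting error only. CDKN1A stands at 2.22% with vehicle and 41.3% with nutlin-3, and MKI67 at 41.3% and 14.7%.

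Cell cycle phases were scored on thinned cells of both libraries together, from the S phase and the G2 and M phase lists. With nutlin-3, 63.1% of cells were called G1 (61.4 to 64.9), 5.07% S and 31.8% G2M (30.1 to 33.5). With vehicle, 5.92% were called G1 (5.08 to 6.85), 18.5% S and 75.6% G2M (74.0 to 77.2). These calls are relative to the pool of both libraries. Within 0.05 of the boundary between G1 and the other calls lay 615 nutlin-3 cells (20.9%) and 377 vehicle cells (13.3%). Cells close to the boundary between S and G2M were not counted. The calls are read beside the lower CPM of both lists and the lower shares of cells with MKI67, TOP2A, CCNB1 and PCNA UMIs. These are no independent check, since the calls were scored from the same lists, which hold MKI67, TOP2A and PCNA though not CCNB1. Unthinned, 56.4% of nutlin-3 and 2.82% of vehicle cells were called G1.

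Whether p21 transcript and cycle transcripts occur in the same cells was asked with 8 core genes of G2 and M phase (MKI67, TOP2A, CCNB1, CDK1, UBE2C, BIRC5, CENPF and TPX2). In the nutlin-3 library CDKN1A was detected in 41.1% of the 2078 cells with a core UMI (39.0 to 43.2) and 41.7% of the 859 cells without (38.4 to 45.1). In the vehicle library it was detected in 2.13% of 2773 cells with a core UMI (1.62 to 2.74) and 5.97% of 67 cells without (1.65 to 14.6). At least 3 core UMIs were found in 40.4% of nutlin-3 cells (38.7 to 42.3) and 85.6% of vehicle cells (84.3 to 86.9), and CDKN1A was detected in 39.0% (36.2 to 41.8) and 1.77% (1.28 to 2.37) of these. Among thinned cells called G1, CDKN1A had a log2 ratio of 2.68 (1.99 to 3.46) rather than 4.74, on 17 UMIs in 168 vehicle cells and 1199 UMIs in 1854 nutlin-3 cells. In the same cells BBC3 was at 1.80 (1.11 to 2.59) rather than 3.96, PHLDA3 at 2.17 (1.44 to 3.01) rather than 3.06, BTG2 at 1.85 (0.85 to 3.07) rather than 2.68 and PIDD1, with 4 vehicle UMIs, at 1.90 rather than 2.88. ACTA2, with 1 vehicle UMI there, was at 3.43 (0.92 to 8.75), and JUN was at 0.22 (−0.54 to 1.09).

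**Figure D3:**
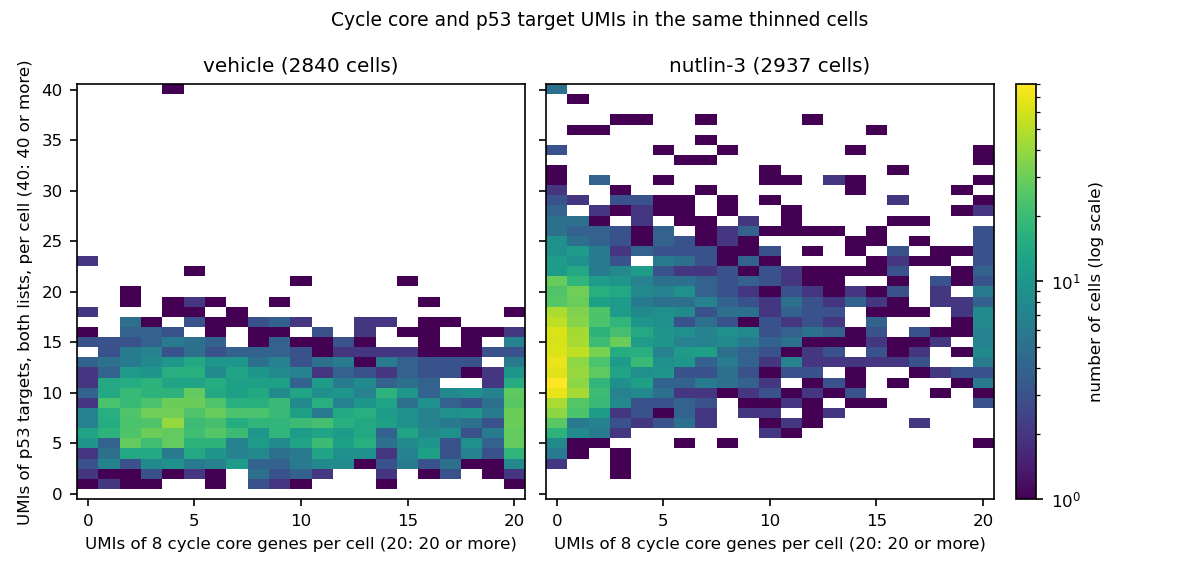
Number of cells (colour, log scale) by UMIs of the 8 core genes (x axis, 20 meaning 20 or more) and of p53 targets of both lists (y axis, 40 meaning 40 or more) after thinning to 5000 UMIs, in the vehicle (left, 2840 cells) and nutlin-3 (right, 2937 cells) libraries. The mean p53 target sum was 8.19 UMIs per cell with vehicle and 15.5 with nutlin-3, and within the nutlin-3 library, with CDKN1A left out, it was 16.2 in cells with at least 3 core UMIs and 13.6 in cells with none.

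Cell-to-cell spread was described for p53 targets with at least 0.1 UMIs per thinned cell, most of them at low counts, where variance over mean stays near that of Poisson noise whatever the cells do. The median Fano factor, the variance over the mean of thinned counts, was 1.07 over 23 measured targets with nutlin-3 and 1.06 over 14 with vehicle, against 1.03 for other genes in each. In the nutlin-3 library MDM2 at 1.48 and CDKN1A at 1.47 had the highest factors, followed by RPS27L at 1.33, which was at 1.40 with vehicle. The sum over all targets had a Fano factor of 1.95 with nutlin-3, at a mean of 15.5 UMIs, and 1.36 with vehicle, at 8.19. A higher mean raises this factor at the same relative spread, so no difference in spread is read from these values.

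Clustering each library on its own gave 6 clusters in each. Fixed markers named 2 vehicle clusters, of 177 and 553 cells, and 2 nutlin-3 clusters, of 874 and 133 cells, as G2 and M phase-like, and a nutlin-3 cluster of 175 cells as S phase-like, and the others stayed unnamed. Among nutlin-3 clusters CDKN1A was at 201 CPM in the S phase-like cluster, 88.9 and 102 CPM in the G2 and M phase-like clusters, 114 and 120 CPM in the large unnamed clusters of 1265 and 687 cells, and 297 CPM in the heat shock cluster of 276 cells. No vehicle cluster exceeded 8.89 CPM. The heat shock cluster is called after its leading genes. It also had 4 fixed p53 response markers at least 1.5-fold higher than the other nutlin-3 cells, with GDF15 among its leading genes. By these markers it would be p53 response-like, but it was left unnamed. Of its 171 thinned cells, only 25 held at least 5 UMIs of HSPA6, HSPA1A, HSPA1B and DNAJB1 together. An unnamed vehicle cluster of 137 cells had the chaperone genes HSP90AA1, HSP90B1 and HSPA5 among its leading genes. Cluster sizes were not compared between libraries because the genes that define them differed, and the nutlin-3 library split into 13 clusters at a resolution of 1.0.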

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

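The alternatives that kept only G1 cells, left out the heat shock cluster or left out the 5% of cells with the most UMIs were chosen after seeing the data. No paired analysis was possible because the labels give 1 sample per group. Of the values that answer a comparison, 93 stayed within their counting interval or within 1.5 times the count, 71 moved beyond it and 8, medians of lysosome and of immediate early and heat shock genes, changed sign. Of the other values, for single named genes and for lists inside the range of their random lists among others, 806 stayed, 412 moved and 4 changed sign. These 4 leave out lists inside that range, of which 7 medians went from below to above 0 with TMM factors: adrenergic, mesenchymal, neuronal, nuclear oxidative phosphorylation, ribosome biogenesis, mitochondrially encoded and interferon response. The counts of values that stayed include alternatives that could change little. Scrublet removal took out 10 cells, and the mitochondrial and gene filter 48 vehicle and 28 nutlin-3 cells. All 56 named genes stayed under each of these.

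Scaling shifts every log2 ratio by the same amount, which is the cause of the next values. With TMM factors, 308 genes were at least 2-fold higher, among them all 175 of the CPM scaling, and 302 were lower, all among its 579. List medians were 1.76 for p53 targets of arrest, 0.87 for p53 targets of cell death, −0.999 for S phase, −1.12 for G2 and M phase, 0.53 for ribosomal proteins, −0.24 for cholesterol synthesis, 0.56 for immediate early and heat shock genes and 0.21 for lysosome genes, which turned positive, and CDK4 turned to 0.0101. DESeq2 size factors gave 292 higher and 326 lower genes, and in the same order 1.75, 0.85, −1.02, −1.14, 0.51, −0.25, 0.54 and 0.19. Totals without ribosomal protein and mitochondrial genes gave 1.68, 0.78, −1.09, −1.21, 0.44, −0.32, 0.48 and 0.12. Per ERCC UMI the medians were 0.52 for p53 targets of cell death, −1.47 for G2 and M phase, 0.19 for ribosomal proteins, −0.58 for cholesterol synthesis and 0.22 for immediate early and heat shock genes. Under these 4 scalings CDKN1A, MDM2 and the p53 and cell cycle medians kept their direction.

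Lower filters count more genes with few UMIs. With at least 20 UMIs, 408 genes were higher and 985 lower, the arrest list had a median of 1.66 and lysosome genes 0.0484. With at least 1 UMI, 1379 were higher and 2765 lower, and medians were 1.66 for the arrest list, 0.90 for the death list, 0.44 for immediate early and heat shock genes and 0.14 for lysosome genes.

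Among G1 cells only, thinned to 5000 UMIs, 6133 genes had enough UMIs. Of these, 176 were at least 2-fold higher, 54 of them among the 175 of all cells, and 175 were lower, 76 of them among the 579. In all thinned cells 89 and 123 of the same genes were at least 2-fold higher and lower. The G1 groups held 168 vehicle and 1854 nutlin-3 cells, so a gene with enough UMIs can rest on few vehicle UMIs, as ACTA2 does on 1. Such sparse counts can by themselves put more genes beyond 2-fold. More genes differing among G1 cells is therefore not read from these numbers. Medians were 1.204 for the arrest list, 0.37 for the death list, −1.14 for S phase, −0.56 for G2 and M phase, 0.17 for ribosomal proteins, −0.0384 for immediate early and heat shock genes and 0.11 for lysosome genes. MDM4 was at 0.0213 (−0.42 to 0.49), an interval that holds its value of −0.32 in all cells. Fewer members had enough UMIs in G1 cells, 24 of the arrest list, 23 of S phase and 21 of G2 and M phase. Immediate early and heat shock genes kept 13 members and lysosome genes 11. In all cells the same members had medians of 1.51, −1.15, −1.25, 0.04 and −0.04, in that order. The S phase median thus hardly moved, and most of the fall of immediate early and heat shock genes from 0.31 came with the members lost. G1 cells were picked with the cell cycle lists, so their 2 medians are not independent of that choice, and the cause of the remaining differences was not tested.

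Without the heat shock cluster the median of immediate early and heat shock genes turned to −0.56, JUN to −0.72 and DNAJB1 to −0.57, since that cluster holds most of their nutlin-3 UMIs. Cholesterol synthesis was at −0.60 and ribosomal proteins at 0.29. FOS, ATF3, GDF15 and HSPA6 had too few UMIs left for a value. Without the 5% of cells with the most UMIs the arrest list was at 1.63 and G2 and M phase at −1.31. The mean of each cell's CPM gave −1.27 for G2 and M phase and 0.27 for ribosomal proteins. The cause of these small differences was not tested.

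More UMIs per cell raise each share of cells with a UMI. Without thinning, CDKN1A was detected in 3.29% of vehicle and 52.3% of nutlin-3 cells and MKI67 in 53.3% and 19.3%. G1 calls were 2.82% and 56.4% and G2M calls 79.7% and 38.9%. CDKN1A was detected in 3.25% and 51.7% of cells with a core UMI, and in 54.3% of nutlin-3 cells without. At 10000 UMIs, CDKN1A was detected in 4.09% and 62.9% of cells and MKI67 in 70.4% and 23.6%. With each library scored separately, G1 calls were 8.45% and 54.9%, G2M calls 73.8% and 36.4%, and S calls 8.75% with nutlin-3. All of these kept the order of the libraries. At a Leiden resolution of 1.0 the nutlin-3 library split into 13 clusters.

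Depth limits genes such as GDF15 and INPP5D, whose 2 vehicle UMIs leave wide intervals, and thinning to 10000 UMIs kept only 611 vehicle and 601 nutlin-3 cells.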

Other observations

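The gene groups in the next paragraph, the tests of the heat shock cluster, the ratios without SIVA1 and of single p53 targets, and the use of G1 cells were chosen after the data or the result were seen.

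Translation factors and noncoding hosts of small nucleolar RNAs include many genes with the 5′ terminal motif that ties translation to nutrient signals. Of 19 subunits of eEF1, eEF2 and eIF3, 9 were at least 1.5-fold higher and 0 at least 1.5-fold lower, with a median log2 ratio of 0.55 that ran from 0.46 per ERCC UMI to 0.80 with TMM factors. EIF3H was at 0.91, EEF2 at 0.88 and EEF1A1 at 0.59, while EIF3B was at −0.55. Of 23 small nucleolar RNA hosts, 7 were higher and 4 lower, with a median of 0.10 (0.01 per ERCC UMI, 0.35 with TMM factors), and SNHG32 was at 1.503, GAS5 at 1.43 and SNHG7 at 1.28. Of 25 histone genes, which are mostly made in S phase, 13 were lower and 3 higher, with a median of −0.69 (−0.78 to −0.44 over the same scalings), H4C3 being at −1.64 and H2AC25 at 2.14. Of 76 mitochondrial ribosomal protein genes 4 were higher and 2 lower, with a median of −0.17 that turned to 0.08 with TMM factors. Of 34 proteasome genes 0 were higher and 5 lower, with a median of −0.32 (−0.41 per ERCC UMI, −0.07 with TMM factors). This median lay inside the range of its random lists (−0.40 to −0.08). The median of mitochondrial ribosomal protein genes lay inside its range too (−0.36 to −0.14). Neither group is read as apart from genes of similar level. Medians of the translation factors, small nucleolar RNA hosts and histone genes lay outside theirs, but these groups were picked after the data were seen. Among other noncoding genes, PURPL, a p53-induced transcript, was at 1.84 and MIR34AHG, host of miR-34a, at 2.67.

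In the nutlin-3 library 40.4% of cells held at least 3 UMIs of the core genes of G2 and M phase. CDKN1A was detected in 39.0% of these (36.2 to 41.8) and in 41.7% of cells with no core UMI (38.4 to 45.1). Free RNA from other cells as the source of all core UMIs would spread them as Poisson noise, but their sum had a Fano factor of 8.55. Cells rich in core UMIs raise that factor, so it leaves free RNA open for cells with few core UMIs. It says nothing about free CDKN1A RNA. A weaker p53 response over the targets as a set is argued against by the summed p53 target UMIs per cell without CDKN1A. In cells with at least 3 core UMIs they were at 1.19 times (1.16 to 1.22) those of cells with no core UMI. Without SIVA1 as well the ratio was 1.16 (1.13 to 1.19). RPS27L, at 1.35 (1.29 to 1.42) on 4887 UMIs in the former cells, stayed in both sums, which lean towards abundant targets. CDKN1A at 0.806 (0.720 to 0.902), SESN2 at 0.486, BTG2 at 0.690 and PLK3 at 0.695 were lower. Cells that nutlin-3 did not reach are argued against by a ratio of 1.99 (1.95 to 2.03) over vehicle cells that also held at least 3 core UMIs. What stays open is whether these cells still divide or may be held in G2 with cycle transcripts left, which RNA counts do not decide.

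The nutlin-3 cluster of 276 cells led by HSPA6, JUN, FOS and ATF3 had no vehicle cluster with any of these 4 genes among its leading genes. Damaged or leaking cells stay open for part of it: its median UMI count was 0.900 of that of the other nutlin-3 cells and its median mitochondrial share lower, 3.62% against 4.92%, but 105 of its cells had fewer than 5000 UMIs, against 368 of the other 3134. Few cells carry the heat shock UMIs, since 30 nutlin-3 cells, 25 of them in the cluster, and 3 vehicle cells, 0.106%, held at least 5 after thinning, and as these genes lead the cluster this leaves handling stress shared by both libraries open. The values that a stronger p53 response needs are there, since its 171 thinned cells held 1.29 times (1.25 to 1.34) the p53 target UMIs of the others, but this was found and tested on the same cells. Handling that differed between the 2 cultures stays open too, as each was processed as 1 library.

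Over all genes the median log2 ratio was −0.27, so most genes were lower relative to the total in the nutlin-3 library. Ribosomal protein genes, which took 41.9% of UMIs with nutlin-3 and 35.2% with vehicle, may account for part but not all of this, since without them and the mitochondrial genes, which took less with nutlin-3, the median was −0.11, just past the limit of −0.1 set beforehand. Capture that is lower for all genes alike cancels in CPM, so the median of −0.37 per ERCC UMI, a constant shift, decides nothing about it. Fewer cycling cells may likewise account for part, since among thinned G1 cells the median was −0.12, against −0.22 for the same 6133 genes in all thinned cells and −0.23 without thinning. Whether total RNA per cell differed stays open, because spike-in and cell counts come from 1 library each.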
